A study of Homo sapiens with 24 samples.

How the data were processed

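The series comprises 24 samples of ChIP-seq in human cells, and 6 of them, each with 1 peak list, were analysed here. These are K562 cells with an empty vector (clone Vec6, the control) or a PU1 knockdown (clone 2.10), treated per the labels with 25 ng/ml BMP4 for 2 h, each profiled with PU1, GATA2 and SMAD1 antibodies. The other 18 samples, among them the input libraries and the CD34+ cell libraries, were not analysed here. Groups were taken from the sample titles together with the other sample labels. The titles of the 6 libraries name neither the SMAD1 antibody nor the empty vector or knockdown. Every group had 1 library.

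Reads had been aligned with Bowtie to hg19, per the submitters' processing notes, and peaks called with MACS2, per the peak names in the deposited files. Aligner version, caller version and settings, treatment of duplicate reads, and which input served as control are not given in the sources used here. Per the labels' protocols the libraries had been amplified by PCR, so reads are not independent molecules. One list was deposited per library, and whether replicates had been pooled before calling is not given in the sources used here. In each list the authors deposited a position, a fold enrichment of the peak over its background (a linear ratio), the −log10 of a p-value, the −log10 of a q-value, and the summit's distance from the peak start. The fold and the −log10 values belong to the authors' caller. They were used to describe, rank and filter peaks within a list. The smallest −log10 q of the 6 lists was 1.30, the value of a q threshold of 0.05.

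Peaks on chromosomes 1 to 22 and X entered every comparison, and those on other sequences were counted apart. Coordinates are printed 1-based. A peak was shared when it overlapped a peak of the other list by at least 1 bp. Each share has an exact Clopper-Pearson 95% interval and, as background, the mean of 200 placements in which the query list was shifted by a random distance around each chromosome. Retention, the share of control peaks with a knockdown peak of the same antibody, was computed in 10 rank classes of the control list by −log10 q. For the retention of peaks with and without a partner factor, shares elsewhere were standardised to the rank classes of the peaks with the partner, and class labels were permuted 10000 times within rank classes.

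The depth behind a peak list was recovered from the deposited columns. The caller's fold is the pileup plus 1 over the background plus 1, and its p-value is a Poisson tail, so both quantities follow from the fold and the −log10 p. All peaks matched the deposited −log10 p within 0.001 in every library; with a pileup unit wrong by 4%, 3.00 to 7.00% matched. Pileups were whole reads in 5 libraries, where the input had been scaled to the ChIP. In the SMAD1 knockdown library the ChIP had been multiplied by 0.298, which puts it at 3.36 times the depth of its input. The lowest background of a list is called its floor. It was the value of 1 peak in the SMAD1 knockdown list and of 9 in the PU1 knockdown list, against 280 to 835 peaks in the other lists. In those short lists the floor, and the depth and thinning that rest on it, may be set too high. If the caller used its preset human genome size of 2.7 Gb, and if the narrowest peak equals the fragment length, the floors correspond, in units of 1000000 reads, to 27.9 and 23.2 for PU1 in control and knockdown cells, 5.88 and 25.0 for GATA2, and 16.2 and 4.55 for SMAD1. The last is the depth of the input to which the ChIP had been scaled, and the ChIP itself comes to 15.3. Thinning means that pileups and backgrounds of the deeper library were multiplied by the ratio of the floors, and peaks at or above the smallest −log10 p of the other list were kept.

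The comparisons, the peaks named and most alternatives were chosen before the data were examined. For each antibody the rule named the 10 peaks highest by −log10 q among those shared, among control peaks without a knockdown peak, and among knockdown peaks without a control peak; the text gives a few of each with positions, leaves out peaks on chromosome 8, and counts the rest. The 3 regions present in all lists were named after their values were seen. Alternatives were a −log10 q of at least 5, a fold of at least 10, merging within 500 bp, all sequences, reciprocal overlap of 50%, summits within 100 or 500 bp, lists of equal length, a local shift of 10 kb, ranks by fold and 20 rank classes. Thinning, the restriction to peaks with a background below 10 times the floor, and a permutation within rank over all 4 partner classes of SMAD1 peaks were added after seeing the data. Genomic location, sequence motifs, the 10 gene lists and the alternatives for distal peaks need an hg19 genome or annotation and were not run.

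The code was tested on simulated data. Of 3000 shared peaks, copied from the PU1 control list with shifts shorter than any of its peaks, 100% were recovered. The 1993 unshared ones had been picked by the same overlap rule, so the 0% called shared was fixed in advance and tests nothing. A planted ChIP scale of 0.31 was recovered as 0.31 from 100 peaks. In 8000 simulated peaks a planted retention difference of 0 points gave 0.0082 and one of 10 points gave 8.59, and the permutation test called the second alone. Each difference was simulated once, with retention far higher than in the PU1 (0.638%) and SMAD1 (0.853%) lists and constant within a rank class. How the test behaves at such low retention, or where retention changes within a class, was therefore not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.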

Results

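The 6 libraries with peak lists came from K562, an immortalised human erythroleukaemia line, in which chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been carried out after 2 h in 25 ng/ml BMP4, the ligand that activates SMAD1. A control clone with an empty vector (Vec6) and a clone with a PU1 knockdown (2.10) were each profiled with antibodies against 3 factors. PU1 is an ETS-family transcription factor of myeloid and lymphoid cells, encoded by SPI1. GATA2 is a zinc-finger factor of blood stem and progenitor cells, and SMAD1 carries the BMP signal to chromatin. Each combination of clone and antibody had 1 library, so no difference between the clones has a replicate check and no p-value is given between them. Intervals are exact Clopper-Pearson 95% intervals over peaks and cover counting error only. Positions are on hg19. Peaks are named by position because no hg19 gene annotation was used here.

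The lists held 18349 PU1 peaks in control cells and 908 in knockdown cells on chromosomes 1 to 22 and X. For GATA2 the numbers were 14763 and 18018, and for SMAD1 they were 8561 and 76. Median peak widths ran from 124 bp in the PU1 knockdown list to 212 bp in the GATA2 control list. Depth was read from the lowest background under any peak of a list, which scales with the number of reads after the caller's scaling. This floor was 1.26 reads in the PU1 control library and 0.832 in the PU1 knockdown library. It was 0.320 and 1.18 for GATA2, and 0.831 and 0.204 for SMAD1. The GATA2 control library was therefore the shallow one of its pair, and the SMAD1 knockdown library had been scaled down to the depth of its input.

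**Figure D1:**
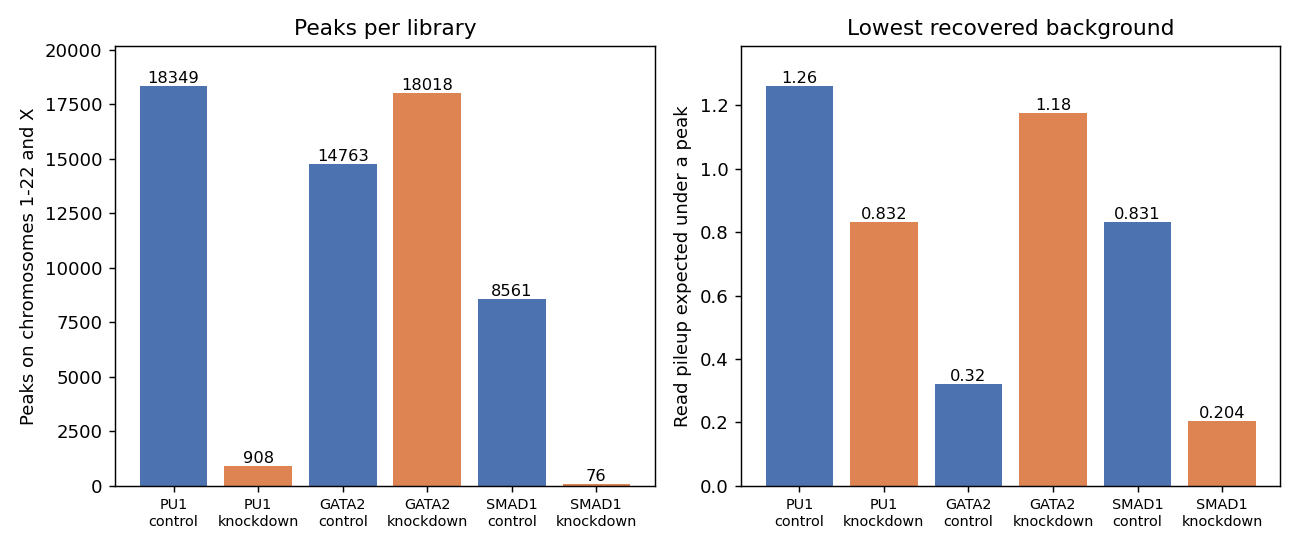
Peaks per library on chromosomes 1 to 22 and X (left bars) and the lowest background recovered under any peak of the list, in reads (right bars), for the control (blue) and knockdown (orange) clone with each antibody; 1 library per bar, so no error bars. PU1 fell from 18349 to 908 peaks and SMAD1 from 8561 to 76, while GATA2 had 14763 and 18018.

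PU1 occupancy was compared first, because PU1 is the knocked-down factor and its own ChIP is the only readout of the knockdown in these files; the SPI1 transcript was not analysed here. The knockdown list was 20.2-fold shorter than the control list. Peaks with a fold of at least 10 numbered 3 in the knockdown and 2929 in the control list. Of the 18349 control peaks, 117 overlapped a knockdown peak (0.638%, interval 0.528 to 0.764), and 119 of the 908 knockdown peaks overlapped a control peak (13.1%, 11.0 to 15.5). The knockdown peaks lay more often at control SMAD1 (27.4%, 24.5 to 30.4) and control GATA2 peaks (25.0%, 22.2 to 27.9) than at control PU1 peaks. This came from 479 knockdown peaks over high background, with 45.1% at SMAD1, 41.5% at GATA2 and 19.0% at PU1 peaks. In the other 429 the shares were 7.69%, 6.53% and 6.53%. Randomly placed control peaks overlapped the knockdown list in 0.0128% of cases on average, and control peaks shifted by 10 kb did so in 0.123%. The strongest control site without a knockdown peak lay on chromosome 9 at 115185050 to 115185403, with a deposited fold enrichment of 35.4 and a −log10 q of 234. It was followed by a site on chromosome 1 at 164681424 to 164681925 (fold 22.6, −log10 q 222) and another on chromosome 9 at 137248880 to 137249149 (fold 34.7, −log10 q 207). All 10 of the strongest such sites were also GATA2 peaks in control cells, and 9 were also SMAD1 peaks. The same counts held for the 10 shared PU1 sites highest in the control list.

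The PU1 sites shared by both clones were few and mostly low in fold. Their median fold enrichment in the control list was 2.21, against 6.05 for control peaks without a knockdown peak. Of the 117 shared control peaks, 91 lay over a background of at least 10 times the floor, which lowers the fold. Retention was 7.84% over such background and 0.151% among the other control peaks. Retention was 0.654% (0.338 to 1.14) in the top 10% of the control list and 1.96% (1.38 to 2.71) in the bottom 10%. The shared site ranked highest in the control list was on chromosome 1 at 25606126 to 25606533, where fold enrichment was 16.1 in control and 3.87 in knockdown cells. The next was on chromosome 17 at 79367719 to 79367958, with 18.5 and 6.77. Folds from separate lists are given side by side and were not tested against each other. Among the 789 knockdown peaks without a control counterpart, the strongest lay on chromosome 4 at 603288 to 603529 (fold 26.7, −log10 q 57.6), also a GATA2 peak in knockdown cells. The next ones, on chromosome 21 at 9825436 to 9825838 and 9825947 to 9826312, had folds of 3.32 and 3.41 over backgrounds of 41.2 and 38.3 reads. A background of at least 10 times the floor lay under 52.8% of knockdown peaks and 6.32% of control peaks. Without such peaks 429 knockdown and 17189 control peaks were left, and 0.145% of the control and 5.83% of the knockdown peaks were shared. At a reciprocal overlap of 50% the shares were 0.332% and 6.72%.

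SMAD1 occupancy was compared to see whether the BMP-activated factor still reached its sites with less PU1. The knockdown list held 76 peaks, 113-fold fewer than the 8561 of control cells. Of these, 74 overlapped a control SMAD1 peak (97.4%, 90.8 to 99.7), against 0.0724% for random placements. They lay at control PU1 peaks (96.1%, 88.9 to 99.2) and control GATA2 peaks (92.1%, 83.6 to 97.0) about as often. The 97.4% fell to 43.4% at a reciprocal overlap of 50%. It fell to 52.5% where both lists kept low-background peaks and to 21.1% in lists of equal length. It held with summits within 100 bp (96.1%) or 500 bp (97.4%). At a −log10 q of at least 5, 39 of 40 knockdown peaks were shared. The low-background and equal-length settings also shortened the control list, which lowers the share by construction. Of the low-background knockdown peaks, 96.7% overlapped the full control list. In the other direction 73 of 8561 control peaks (0.853%, 0.669 to 1.07) had a knockdown peak. This share was 2.33% after thinning the control list and 21.1% in lists of equal length. The 73 came mostly from the top of the control list, with a median −log10 q of 53.7 against 12.2 for the rest. Retention was 4.78% (3.45 to 6.43) in the top 10% of the list and 1.87% (1.07 to 3.02) in the next 10%.

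The SMAD1 site kept in knockdown cells that ranked highest in the control list was on chromosome 19 at 29097190 to 29097637, with fold enrichments of 27.1 in control and 13.2 in knockdown. On chromosome 1, the sites at 47646873 to 47647241 and 160509936 to 160510331 had control folds of 21.6 and 19.9 and knockdown folds of 4.80 and 4.87. All 10 of the kept sites highest in the control list were also PU1 and GATA2 peaks in control cells. So were all 10 of the strongest control sites without a knockdown SMAD1 peak. The strongest control site of all, on chromosome 6 at 27741601 to 27742169 (fold 34.5, −log10 q 218), had no SMAD1 peak in knockdown cells but did have a GATA2 peak there. Of the 10 strongest sites without a knockdown SMAD1 peak, 9 had a GATA2 peak in knockdown cells. So did 6 of the 10 kept sites highest in the control list, and 58.6% of the 500 strongest control SMAD1 peaks. The 2 knockdown SMAD1 peaks with no control SMAD1 peak, on chromosome 21 at 36855636 to 36855766 and on chromosome 2 at 176800453 to 176800585, were both control PU1 and GATA2 peaks. The knockdown library had been scaled by 0.298 before calling, and thinning the control list to its depth left 2449 peaks, 32.2 times the knockdown list.

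GATA2 was compared to ask whether a partner factor moved in the same cells. The knockdown list was longer, with 18018 peaks against 14763, and largely held other positions. Of the control peaks, 3271 (22.2%, 21.5 to 22.8) had a knockdown peak, and 3279 of the knockdown peaks (18.2%, 17.6 to 18.8) had a control peak; random placements gave 0.277% and 0.233%, and shifts by 10 kb 0.864% and 0.708%. Retention was higher for stronger peaks, at 45.9% (43.3 to 48.5) in the top 10% of the control list and 8.94% (7.54 to 10.5) in the bottom 10%. The difference in number turned with depth: thinning the knockdown list to the control library's floor left 10130 peaks, 0.686 times the control list. Counting peaks with a fold of at least 10 also turned it, with 1495 in knockdown and 3780 in control cells.

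Among GATA2 sites in both clones, the one ranked highest in the control list lay on chromosome 1 at 164681420 to 164681928, with a fold of 47.7. The knockdown peak, with a fold of 3.32, lay at 164681853 to 164682068 and overlapped only the end of the control peak, so the 2 folds may not belong to 1 site. A site on chromosome 3 at 5150015 to 5150331 had folds of 55.6 in control and 7.89 in knockdown cells. The strongest control site without a knockdown peak, on chromosome 12 at 120103010 to 120103796 (fold 45.1, −log10 q 215), was also a control PU1 and SMAD1 peak. All 10 of the strongest such sites were control PU1 peaks and 9 were control SMAD1 peaks. The 10 shared GATA2 sites highest in the control list gave the same counts. Of the strongest knockdown sites without a control GATA2 peak, those on chromosome 5 at 176921105 to 176921551 (fold 23.4, −log10 q 221), on chromosome 1 at 165197965 to 165198248 (fold 41.0, −log10 q 205) and on chromosome 16 at 21801885 to 21802162 (fold 23.2, −log10 q 198) had a peak in no other list. None of the 10 strongest such sites was a control PU1 peak, and 1 was a control SMAD1 peak. Most sites of this class were in no other list. In all, 14739 knockdown peaks had no control GATA2 peak, and 13889 merged regions held a knockdown GATA2 peak alone. The counts among the 10 strongest therefore do not set them apart from the class. Of the 500 strongest knockdown peaks, shared ones included, 36.4% were control GATA2 peaks, 29.8% control SMAD1 peaks and 22.2% control PU1 peaks.

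**Figure D2:**
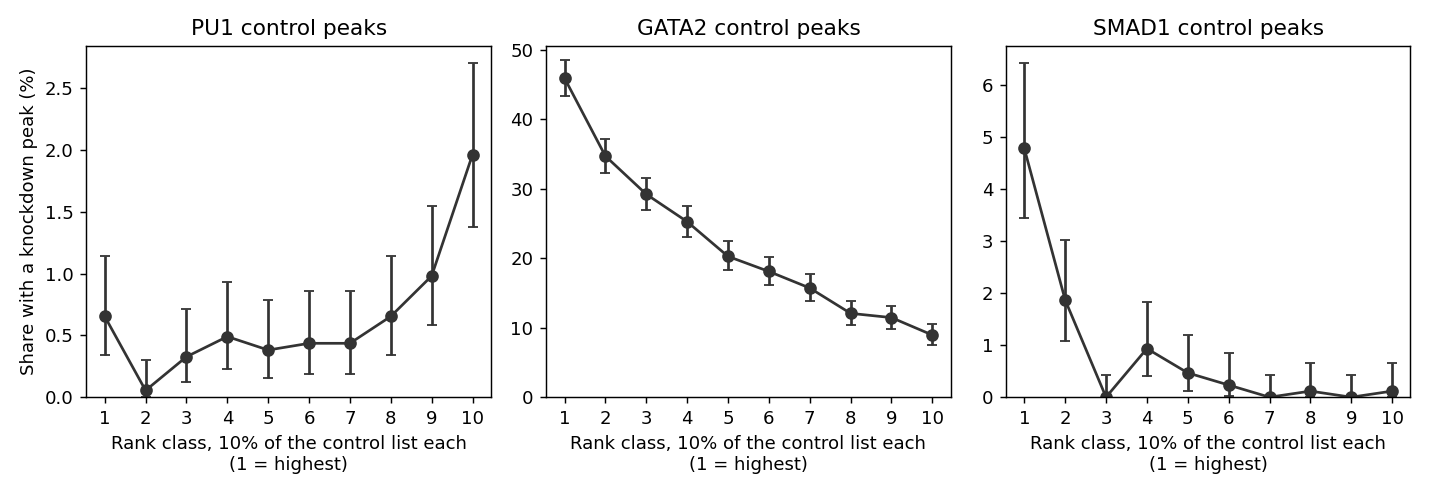
Share of control peaks with an overlapping knockdown peak of the same antibody (y axis, %, a separate scale in each panel), by rank class (10% of the control list each), ranked by the deposited −log10 q (x axis, 1 is the highest). Points are shares and bars exact 95% intervals over peaks. GATA2 falls from 45.9% to 8.94%, SMAD1 starts at 4.78%, and PU1 is at 0.654% in the highest and 1.96% in the lowest class.

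In control cells the peak lists of the 3 factors overlapped in large part. SMAD1 peaks overlapped GATA2 peaks in 72.6% of cases (71.6 to 73.5) and PU1 peaks in 66.8% (65.8 to 67.8). GATA2 peaks overlapped PU1 peaks in 59.4% (58.6 to 60.2) and SMAD1 peaks in 41.9% (41.1 to 42.7). PU1 peaks overlapped GATA2 peaks in 48.1% (47.3 to 48.8) and SMAD1 peaks in 31.2% (30.5 to 31.8). Random placements gave at most 0.444% for any of these pairs, and shifts by 10 kb 0.510 to 1.08%. Neither background matches sites on how readily they give ChIP signal. Binding of each factor was therefore not told apart from signal common to the 3 antibodies. Peaks of both other factors lay at 58.2% of SMAD1 peaks, 33.6% of GATA2 peaks and 27.2% of PU1 peaks. Among the 500 strongest peaks the sharing was nearly complete: 99.6% of SMAD1 peaks were at GATA2 peaks, 98.6% of GATA2 peaks were at PU1 peaks and 92.6% of PU1 peaks were at SMAD1 peaks.

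Merging all lists gave 40315 regions, of which 4970 held peaks of all 3 factors in control cells. In knockdown cells 1661 of the 4970 (33.4%, 32.1 to 34.8) kept a GATA2 peak, 67 (1.35%, 1.05 to 1.71) a SMAD1 peak and 47 (0.946%, 0.696 to 1.26) a PU1 peak. No knockdown peak of any factor was left at 3249 of them. Knockdown cells had 6 regions with peaks of all 3 factors, and 3 regions were in all 6 lists: chromosome 1 at 156186194 to 156186662, chromosome 6 at 135644190 to 135644759 and chromosome 21 at 9826865 to 9827583. The last lies beside the PU1 knockdown peaks on chromosome 21 named above, which had backgrounds of 41.2 and 38.3 reads. GATA2 peaks of knockdown cells overlapped PU1 peaks of the same cells in 0.827% (0.700 to 0.97), and 16.6% (14.3 to 19.2) of the 908 PU1 peaks lay at GATA2 peaks. A total of 13889 regions held a knockdown GATA2 peak alone.

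**Figure D3:**
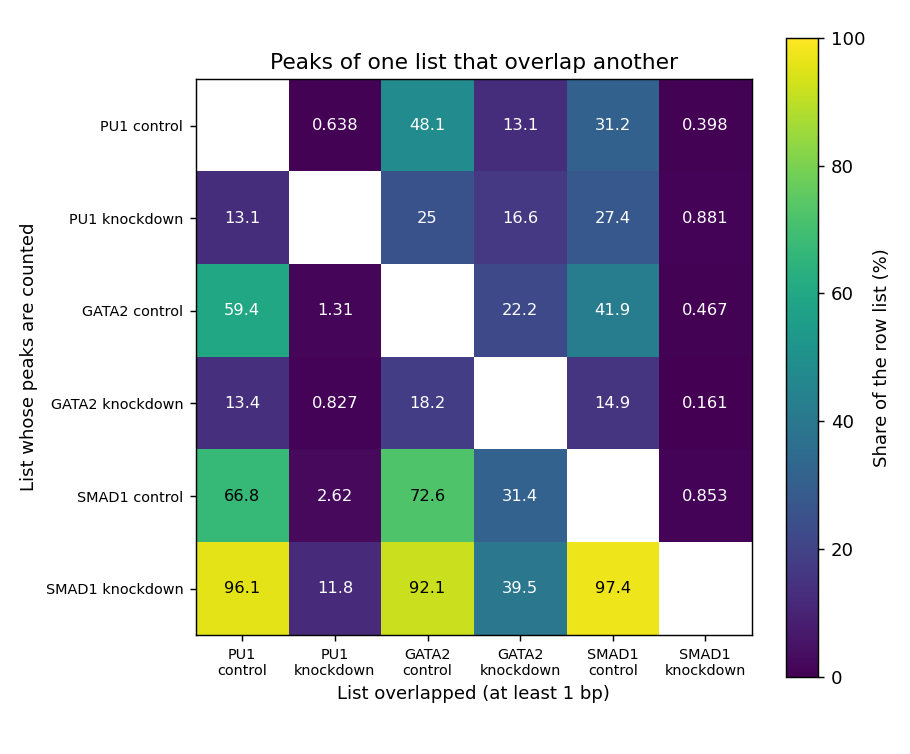
Share of each list (rows, %) that overlaps each other list (columns) by at least 1 bp, as printed and coloured on a scale from 0 to 100%. The control lists overlap each other in 31.2 to 72.6% of peaks, control GATA2 overlaps knockdown GATA2 in 22.2%, and the 76 knockdown SMAD1 peaks lie at control SMAD1 peaks in 97.4%.

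Whether sites with a partner factor behaved differently was tested between peaks of the same rank in the control list. Shares elsewhere were therefore standardised to the ranks of the peaks with the partner. Before standardising, 23.5% of control GATA2 peaks at PU1 sites and 20.2% of the others were kept. Against peaks of the same rank the direction turned: 23.5% were kept at PU1 sites and 36.5% elsewhere, a difference of −13.1 points. Permuting the classes within rank 10000 times gave a central 95% of −2.86 to 2.83. Control GATA2 peaks at SMAD1 sites were kept more often, 35.6% against 17.1% at the same rank (12.4% before standardising), a difference of 18.5 points (permuted −2.56 to 2.52). PU1 peaks were kept in 1.54% of cases at SMAD1 sites and 0.233% elsewhere, a difference of 1.31 points (permuted −0.331 to 0.282), and the difference at GATA2 sites was 0.465 points (permuted −0.383 to 0.270). Of the 117 kept PU1 peaks, 91 lay over high background; among the other PU1 peaks the differences were 0.224 points at SMAD1 sites (permuted −0.273 to 0.218) and 0.247 points at GATA2 sites (permuted −0.326 to 0.196). SMAD1 peaks at PU1 sites were kept in 1.22% of cases against 0.270% elsewhere at the same rank (0.106% before standardising), a difference of 0.954 points (permuted −1.20 to 0.925). That last difference rested on 3 kept peaks elsewhere. Among the peaks elsewhere, those with GATA2 alone kept 0 against 5.90 expected from rank, and those with neither partner 3 against 2.78. SMAD1 peaks at GATA2 sites differed by −0.196 points from the rest, inside the permuted range of −6.48 to 1.14. With ranks by fold that difference was 0.919 points (permuted −1.19 to 0.793), so its sign depended on the ranking. These ranges describe the peaks of these libraries, since peaks are not replicates of the clones.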

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

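Thinning of the deeper list, the restriction by background, the comparison of the GATA2 background floors and the departure over all 4 partner classes of SMAD1 peaks were tests chosen after the data were seen. In the lists as deposited, the number of peaks in knockdown over control cells was 0.0495 for PU1, 0.00888 for SMAD1 and 1.22 for GATA2, which put GATA2 apart in direction. That direction did not hold: the GATA2 ratio was 0.686 after thinning and 0.396 at a fold of at least 10. The difference between antibodies was not tested, since each value rests on 1 library per clone.

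The shorter PU1 list was weighed against read depth. The floor of the knockdown library was 0.660 times that of control, and thinning the control list to it left 18.2 times the knockdown list, which argues against depth as the whole cause. The median background under the knockdown peaks, 2.02 times that of control, says nothing on depth, because 52.8% of those peaks lay over high background against 6.32% in control. A weaker immunoprecipitation and less PU1 on chromatin, as the knockdown would give, may each account for the rest and were not separated, because the test prepared for a uniform loss needs the genome sequence.

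The shorter SMAD1 list did come from a shallower comparison, with a floor 0.245 and a median background 0.194 times that of control, but thinning the control list still left 32.2 times the knockdown list, so depth does not account for the whole difference. A uniform loss of SMAD1 yield, with no dependence on the site, is argued against only weakly and by a narrow margin. Retention at the same rank was 0.954 points higher at PU1 sites, where the central 95% of permuted labels ended at 0.925. Only 3 peaks were kept elsewhere. Rank was matched only in classes, and of the 41 peaks kept in the top 10% of the list, 37 lay among the 500 strongest. The difference also passed the permuted range with 20 rank classes (0.987 against 0.918), with summits within 500 bp (0.953 against 0.895) and with ranks by fold (1.16 against 0.561). Over lower background it did so too (0.847 against 0.675), but with 36 peaks kept at PU1 sites and 0 elsewhere. These alternatives draw on largely the same kept peaks and are not independent of each other. A departure over all 4 partner classes as large as the one seen was reached in 2.89 to 3.8% of permutations, between the bounds of 1% and 5%, and decides nothing by itself. With 10 rank classes, 0 peaks with GATA2 alone were kept against 5.90 expected from rank, and 3 with neither partner against 2.78. With both partners 67 were kept against 63.0 expected, and with PU1 alone 3 against 1.32. The shortfall away from PU1 sites thus lay in peaks with GATA2 alone. A weaker SMAD1 immunoprecipitation may still account for much or all of the loss. A difference between sites rests on these few kept peaks, and its source is open.

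The longer GATA2 list of knockdown cells can follow depth alone. The control library, with fewer peaks, had a floor 0.272 and a median background 0.264 times that of the knockdown library, and thinning turned the ratio. The shortfall of the thinned knockdown list, at 0.686 times the control list, is not accounted for by this depth, and its cause was not tested. The GATA2 positions are another matter: control GATA2 peaks were shared with control PU1 in 59.4% and with knockdown GATA2 in 22.2%. Low depth of the knockdown library is argued against by its floor, 3.68 times that of control. Reads of one control library inside the other cannot be told apart from shared sites: over the 500 strongest GATA2 peaks the spread of the pileup ratio was 2.74 times that of Poisson counting against PU1, past the 1.5 set beforehand, but that bound left out noise from amplification, which no pair of libraries here measures alone. A change of GATA2 sites with less PU1, a difference between clones or immunoprecipitations, and an exchanged sample may each be the source and were not tested.

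Peaks outside chromosomes 1 to 22 and X, which entered none of the comparisons apart from the alternative with all sequences, numbered 217 in the PU1 control list, 13 in the PU1 knockdown list, 33 in the GATA2 control list, 15 in the GATA2 knockdown list and 32 in the SMAD1 control list, each above the 3 that a count of 0 allows.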

How the results depend on the processing

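Thinning and the restriction by background were chosen after the data were seen. PU1 and SMAD1 lists were shorter in knockdown cells under every setting tried. The ratio of numbers, knockdown over control, was 0.00102 for PU1 and 0.396 for GATA2 among peaks with a fold of at least 10, against 0.0495 and 1.22 as deposited. It was 0.00535 for SMAD1 at a −log10 q of at least 5 and 0.0250 for PU1 below 10 times the background floor. Thinning gave 0.0310 for SMAD1 and 0.686 for GATA2, so that GATA2 turned with depth and with the fold limit.

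Shares of control peaks with a knockdown peak, for PU1, GATA2 and SMAD1 in this order, were 0.332, 16.9 and 0.385% at a reciprocal overlap of 50%, and 0.273, 21.3 and 0.522% at a −log10 q of at least 5. They were 0.991, 18.9 and 21.1% in lists of equal length, 0.145, 15.9 and 0.481% with low background, and 0.490, 14.2 and 2.33% after thinning. Shares of knockdown peaks with a control peak, in the same order, were 6.72, 13.8 and 43.4% at a reciprocal overlap of 50%. They were 0.991, 19.0 and 21.1% in lists of equal length, 5.83, 13.8 and 52.5% with low background, and 9.14, 20.6 and 75.0% after thinning. A −log10 q of at least 5 gave 7.90% for PU1 and 17.4% for GATA2. By summits within 100 bp, GATA2 shares were 18.8% of control and 15.4% of knockdown peaks. Within 500 bp they were 24.1% and 19.7%, and 15.5% of PU1 knockdown peaks were shared. The share of SMAD1 knockdown peaks was 96.1% by summits within 100 bp and 97.4% within 500 bp. With low background it fell to 52.5% by construction, because the control list lost peaks too: 96.7% of the same 61 knockdown peaks overlapped the full control list. Equal lengths and thinning shortened the PU1 and SMAD1 control lists, so the shares of their knockdown peaks could only fall. Both shortened the GATA2 knockdown list, so the share of GATA2 control peaks could only fall. The cause of the other shifts was not tested.

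Overlaps within control cells exceeded random placement 211- to 312-fold and shifts by 10 kb 61.2- to 82.4-fold, so the excess depends on the background. At a reciprocal overlap of 50%, PU1 peaks lay at GATA2 peaks in 44.7% and at SMAD1 peaks in 29.3%, GATA2 peaks at PU1 in 55.6% and at SMAD1 in 39.3%, and SMAD1 peaks at PU1 in 62.8% and at GATA2 in 67.8%. At a −log10 q of at least 5, PU1 peaks lay at SMAD1 in 32.0%, GATA2 peaks at PU1 in 63.1% and at SMAD1 in 45.5%, and SMAD1 peaks at PU1 in 69.0% and at GATA2 in 74.6%.

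The retention differences of GATA2 at PU1 and at SMAD1 sites and of PU1 at either partner kept their sign and lay outside the permuted range with ranks by fold, 20 rank classes and summits within 500 bp, as did SMAD1 at PU1 sites. With low background they did so too, but PU1 at SMAD1 sites dropped from 1.31 to 0.224 points. For SMAD1 at PU1 sites that setting left 0 kept peaks elsewhere. SMAD1 retention at GATA2 sites changed sign, to 0.919 points with ranks by fold (permuted −1.19 to 0.793), 0.0447 points with 20 rank classes and 0.669 with low background; the cause was not tested. A share counted as kept inside its 95% interval, a ratio of numbers within 1.5 times, and a retention difference with the same sign on the same side of the permuted range. By these limits 42 of 96 alternative values were kept, 49 moved and 5 reversed. Thinning, which also applied the other list's smallest −log10 p, removed 43.8% of the GATA2 knockdown, 71.4% of the SMAD1 control and 9.83% of the PU1 control peaks. With each list's own smallest −log10 p, depth alone removed 44.1, 42.0 and 3.52%. No paired analysis was possible because each group held 1 library. Alternatives for distal peaks, location, motifs and gene lists were not run.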

Other observations

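The split of GATA2 retention by both partners was examined after the other results were seen. Control GATA2 peaks that overlapped SMAD1 but not PU1 were kept in knockdown cells in 558 of 1221 cases (45.7%, exact interval 42.9 to 48.5). Those with both partners were kept in 33.1% (31.8 to 34.5), those with neither in 13.7% (12.8 to 14.7), and those with PU1 alone in 10.8% (9.85 to 11.8). Among the stronger 50% of the control list the order was the same for SMAD1 alone (55.8%, 51.8 to 59.7), both (36.1%, 34.6 to 37.6), neither (23.4%, 20.5 to 26.4) and PU1 alone (14.0%, 12.4 to 15.7). The knockdown GATA2 list covered 58.6% (54.1 to 63.0) of the 500 strongest control SMAD1 peaks, 51.4% (46.9 to 55.9) of the 500 strongest control GATA2 peaks and 38.8% (34.5 to 43.2) of the 500 strongest control PU1 peaks. These are shares of peaks in 1 library per group.

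The PU1 knockdown list stood apart from the other lists in where its peaks lay. Peaks with at least 2 others within 10 kb made up 31.5% of it, against 5.26 to 11.3% of the other lists. Chromosome 19 held 8.81% of its peaks (7.05 to 10.8) and 2.68% of the PU1 control peaks (2.45 to 2.92), while chromosome 3 held 1.87% (1.09 to 2.98) and 6.61% (6.25 to 6.97). Its 479 peaks over high background overlapped control SMAD1 peaks in 45.1% (40.6 to 49.7), and its other 429 peaks did so in 7.69% (5.35 to 10.6). In the SMAD1 knockdown list chromosome 21 held 8 of 76 peaks (10.5%, 4.66 to 19.7), against 1.18% (0.962 to 1.43) of the SMAD1 control list.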
